A study of Mus musculus with 59 samples.

How the data were processed

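The study used bone marrow-derived macrophages, cells grown from mouse bone marrow in medium conditioned by L929 fibroblasts, from wild-type (WT) C57Bl/6 mice and from mice with a disrupted Tnf gene (KO). The labels describe the mice as matched for age and sex. Macrophages were left unstimulated or were given tumour necrosis factor (TNF), the synthetic lipopeptide Pam3CSK, which engages Toll-like receptor 2, or lipopolysaccharide (LPS), which engages Toll-like receptor 4. The samples analysed here were 59: 41 single-cell RNA-seq samples, 14 H3K4me1 ChIP-seq libraries and 4 input libraries, which were not used here. Single-cell doses were 10 ng/ml for TNF and 10 ng/ml for Pam3CSK; ChIP-seq doses were 10 ng/ml for TNF, 100 ng/ml for Pam3CSK and 100 ng/ml for LPS. Pam3CSK was therefore given at different doses in the 2 assays.

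Each single-cell sample was one column of a Fluidigm C1 high-throughput chip, a device that captures single cells in chambers and copies the 3′ ends of their mRNA. The deposited expected counts per gene and cell came from RSEM, per the submitters' processing notes, and the deposited table held 545 cells and 8906 genes, in which every gene had at least 270 counts in all and was seen in at least 14 cells. These are read counts without molecular identifiers, so intervals and floors given here cover counting error only. The expected counts were rounded to whole numbers and summed over the cells of each chip column, which gave 41 sums from 570405 to 6697999 counts. Cells held 99297 to 685420 counts, with a median of 171181, and a median of 3030 detected genes. No filter on cells was added, no doublets were called and no clusters were made. Nothing in the labels says that columns came from separate cultures or mice, or names the chip of a column. The p-values therefore measure only the spread between these samples, which may be technical. Samples with the same column number in different groups came from different chips. KO and WT shared such numbers under each stimulus, as did WT TNF and WT unstimulated, so these contrasts cannot be told apart from chip. Unstimulated and TNF columns were numbered 1 to 10 and Pam3CSK columns 11 to 20, so Pam3CSK differs from both in chip position. A chi-square comparison of the counts of columns within a group gave 30.4 to 118 per degree of freedom over 152 pairs, and 0 pairs held identical values.

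H3K4me1, a histone mark of enhancers, was measured with an anti-H3K4me1 antibody. Reads were aligned to mm10 (GRCm38), and Bowtie2, Picard, MACS2 2.1.0 and deepTools were used, per the submitters' processing notes. The deposited counts were whole numbers of reads in 89300 regions shared by all libraries, with a median width of 2035 bp and a range from 351 to 166742 bp. The 14 libraries held 9914257 to 27517434 reads in regions, and 89274 regions were tested. Groups had 2 libraries each, except LPS with 1 per genotype. Within the 6 pairs of libraries of a group the chi-square comparison gave 4.01 to 5.98 per degree of freedom.

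Each assay was fitted in one edgeR 4.0.16 quasi-likelihood model over all groups (R 4.3.3), with TMM scaling and the default filter on low counts, and Benjamini-Hochberg adjusted p under 0.05 was called changed. A fit over all groups gives every group one estimate of spread, so a lone LPS library is assumed to vary like the other groups. The 7 single-cell comparisons were TNF against unstimulated and Pam3CSK against unstimulated in WT, Pam3CSK against TNF in each genotype, KO against WT under each stimulus, and the difference of Pam3CSK against TNF between the genotypes. No unstimulated KO cells were analysed here. The 12 H3K4me1 comparisons set each stimulus against unstimulated and Pam3CSK against TNF in each genotype, KO against WT in unstimulated cells and averaged over unstimulated, TNF and Pam3CSK, and the difference of the TNF and of the Pam3CSK response between genotypes. Mean values are CPM, read counts scaled to a common library size, with the SD over samples. Folds are ratios of mean CPM; where a group held 0 counts, the fold is a bound computed against 3 counts over the whole group. For genes with 1 to 3 counts in a group, the values of both groups are given without a fold.

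Title numbers 1 and 2 of the ChIP libraries paired them: deviations from the group means correlated between libraries of the same number in all 15 pairs of groups, with r from 0.53 to 0.638, and the first principal component (36.3% of the variance) put number 1 at or below −30.8 and number 2 at or above 71.8. The labels conflict here: the replicate characteristic gives the other number for both libraries of KO unstimulated, KO TNF and KO Pam3CSK and for WT LPS. The fit without the number was the one fixed before the data were examined, so it is the main one, and the fit with the title number as a block stands beside it where it changed a call or moved a count by over 1.5 times. Chip column numbers did not pair the single-cell samples.

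Fixed before the data were examined were the sample groups, tests, alternatives, gene lists and the rule for naming genes. That rule takes Tnf first, then per comparison the 10 largest increases and the 10 largest decreases among changed genes with a mean of at least 50 CPM in the higher group, then up to 4 members per list with the smallest p. For regions it takes the 5 largest gains and the 5 largest losses among changed regions whose mean count is at or above the median, then up to 4 per list. The 14 lists were inflammatory cytokines and chemokines, NF-kB pathway regulators and feedback, interferon-stimulated genes, immediate-early genes, TNF and TLR2 receptors and adaptors, macrophage identity, antigen presentation, cell cycle, NRF2 and oxidative stress, glycolysis and hypoxia, cholesterol and LXR, actin cytoskeleton and adhesion, ribosomal protein and mitochondrially encoded genes. Markers of other cell types were fixed as well, for neutrophils, dendritic cells, B cells, T and NK cells, mast cells and basophils, erythroid cells, stromal cells and osteoclasts. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 14 lists of a comparison, and again with an estimated correlation and with fry. Gene symbols of the single-cell table matched the mouse gene name table for 8635 genes.

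Regions were given to the nearest protein-coding gene whose span lay within 50 kb, on GRCm38 coordinates. The design had planned the nearest transcription start, which could not be used because the gene table used here carries no strand. Of the tested regions, 77805 (87.2%) lay within 50 kb of one of 21887 coding genes and 54514 (61.1%) overlapped one. A gene named beside a region is its neighbour, with no measured link to it.

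Single cells were also assigned to a stimulus. Each cell was thinned to 99297 counts, and a nearest-centroid rule on 104 genes of the first 4 lists, without Tnf, was trained without the column being tested (Python 3.11.15, scikit-learn 1.9.0). The same was done on 100 random lists matched on mean expression. The share of cells with a count and the Fano factor (variance over mean) of 10 inflammatory genes were compared between columns by exact permutation tests in a family of 107 tests. Tests were two-sided.

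The edgeR steps were tested on simulated counts with 200 changed genes or regions. The changed ones were drawn from those at or above the median abundance, so the recovery rates do not cover those below it. In the simulated comparison of WT TNF with unstimulated sums over 8877 genes, 5% of 2-fold and 40% of 4-fold changes were recovered. For KO against WT, 3% and 44% were recovered under TNF over 8884 genes, and 6% and 44% under Pam3CSK over 8885 genes. For H3K4me1, WT TNF against unstimulated recovered 13% and 85% over 88999 regions without the block and 97% and 100% with it. KO against WT, averaged over unstimulated, TNF and Pam3CSK, recovered 77% and 99% over 89027 regions without the block, and 100% and 100% with it. With the block, 14 and 16 unchanged regions were called. The simulated H3K4me1 counts were drawn from the blocked fit, with its title number term and its spread. High recovery with the block therefore holds under that model only. It does not test how well the model describes the real libraries. In simulated cells, every other gene of the 104 used for assignment was changed. With no change, 2-fold and 4-fold changes, cells were assigned rightly at 47.2%, 83.1% and 99% in WT and at 50.4%, 84.7% and 99.6% in KO.

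Alternatives were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter on low counts, limma on mean log2(CPM + 1) per column, leaving out the cells in the lowest 10% of totals, column or replicate numbers as blocks, scaling by total counts in regions, a 10 kb limit for genes, other settings of the cell assignment and leaving out each ChIP library in turn. Chosen after seeing the data were the fit without chip columns of fewer than 8 cells (3 of KO TNF and 2 of WT unstimulated), the fit without regions on X and Y, fits within each title number, leave-one-out within the blocked fit, and the blocked fit with a list test at an estimated correlation.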

Results

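Gene expression was measured in 545 single macrophages from 41 chip columns, and H3K4me1 in 14 ChIP-seq libraries. The single-cell groups were WT unstimulated (8 columns, 92 cells), WT TNF (6 columns, 95 cells), WT Pam3CSK (8 columns, 123 cells), KO TNF (9 columns, 99 cells) and KO Pam3CSK (10 columns, 136 cells). Column sums ran from 663237 to 3239048 counts in WT unstimulated, from 2047316 to 3614127 in WT TNF, from 1040783 to 4050858 in WT Pam3CSK, from 570405 to 6697999 in KO TNF and from 1375700 to 3811044 in KO Pam3CSK. The ChIP libraries held 9914257 to 15734435 reads in regions for title number 1 and 20198384 to 27517434 for title number 2. Comparisons of the single-cell groups asked how macrophages answer TNF and Pam3CSK and whether KO cells answer them differently. The ChIP comparisons asked the same of H3K4me1.

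Tnf, the targeted gene on chromosome 17 from 35199367 to 35202007, was read at 6.36 ± 16.9 CPM in WT unstimulated columns (SD, n = 8), 134.5 ± 83.4 in WT TNF (n = 6), 1121 ± 200.2 in WT Pam3CSK (n = 8), 133.5 ± 69.3 in KO TNF (n = 9) and 567 ± 193 in KO Pam3CSK (n = 10). The KO columns thus carried Tnf reads, from 300.1 to 867 CPM under Pam3CSK. Reads came from 3′ ends, which may lie outside the deleted part of the gene, so these values check nothing about the genotype labels. Of 62 planned markers of other cell types 3 were measured. The neutrophil collagenase gene Mmp8 stood at 18.6 ± 29.3 CPM in WT unstimulated, 22.9 ± 29.3 in WT TNF, 20.7 ± 18.2 in KO TNF, 7.04 ± 11.2 in WT Pam3CSK and 41.8 ± 29.9 in KO Pam3CSK. The immunoglobulin gene Ighm, a B cell marker, stood at 206.7 ± 124 CPM in WT unstimulated, 300.7 ± 108 in WT TNF, 91.5 ± 86.6 in WT Pam3CSK, 53.9 ± 36.2 in KO TNF and 42.1 ± 51.9 in KO Pam3CSK. The osteoclast protease gene Ctsk stayed between 1.61 and 9.08 CPM as a group mean. Median detected genes per cell were 2731 in WT TNF, 2847.5 in WT unstimulated, 3020 in WT Pam3CSK, 3231 in KO TNF and 3346.5 in KO Pam3CSK, and the median share of mitochondrial reads was 5.4% in KO TNF and 6.15% to 7.36% in the other groups.

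TNF raised 101 genes and lowered 5 in WT macrophages relative to unstimulated cells, among 8906 tested. Several genes rose from almost nothing. Cxcl2, a neutrophil chemokine, reached 289.7 ± 171 CPM (n = 6) and had 0 counts in the 8 unstimulated columns, so it was at least 1730-fold higher (edgeR adjusted p = 6.95e-21). Irg1, which encodes the enzyme that makes itaconate, reached 398 ± 150.4 CPM against 0.0478 ± 0.135 (1 count; adjusted p = 3.71e-28). The acute-phase gene Saa3 reached 82.4 ± 67 CPM against 0.108 (2 counts), and the interferon-inducible GTPase gene Gbp2 reached 69.9 ± 68.4 against 0.159 (3 counts). The adhesion molecule gene Icam1 rose 32.3-fold, from 10.1 ± 18.9 CPM, with 55.5 in 1 column and at most 12.3 in the others, to 325 ± 105 CPM, and Clec4e, a pattern recognition lectin gene, rose 18.9-fold, from 36.8 ± 39 to 696 ± 245 CPM.

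NF-kB regulators and feedback genes moved most widely: 15 of 35 rose and none fell, 22 adjusted over the list alone, with a median log2 fold change of 1.77 (camera adjusted p = 1.25e-53). Nfkbia, which encodes the inhibitor that ends NF-kB signalling, rose 15.5-fold, to 644 ± 181 CPM, and the mitochondrial superoxide dismutase gene Sod2 rose 3.92-fold. Traf1, an adaptor of TNF receptors, rose 28.7-fold. Among cytokines and chemokines 7 of 21 rose, 9 over the list alone, with a median of 0.97 (adjusted p = 3.73e-13). These included Il1b, Cxcl1 and Ccl5, which varied widely between the 6 columns. Il1b, at least 108-fold higher as a mean, stood at 18.1 ± 41.6 CPM, with 103 CPM in 1 column and at most 3.83 in the others. Cxcl1, at least 118-fold higher, stood at 19.7 ± 31.7 CPM with counts in 3 columns, and Ccl5, 295-fold higher, at 49.2 ± 76.4 CPM against 4 counts in unstimulated columns, with 198 CPM in its highest column and 53.3 in the next. Among interferon-stimulated genes 4 of 29 rose, 7 over the list alone (median 1.77, adjusted p = 1.36e-09): Gbp2, Gbp3, Ifit2, which was at least 96.1-fold higher, and Ifitm3, which rose 2.04-fold. Receptor and adaptor genes had 3 of 22 higher, 3 over the list alone (median 0.60, adjusted p = 0.00127), namely the LPS co-receptor gene Cd14 (4.34-fold), Tlr2 (6.51-fold) and the kinase gene Irak2 (30.3-fold). Immediate-early genes had 2 of 19 higher, 3 over the list alone (median 0.19, adjusted p = 0.0159), of which Ier3 rose 36.9-fold. Antigen presentation genes had 1 of 18 higher, the class I gene H2-K1 at 2.47-fold, and 6 over the list alone (median 1.69, adjusted p = 9.54e-08). Tnf itself rose 21.2-fold (adjusted p = 3.91e-05), a call that DESeq2 did not make (adjusted p = 0.5). That fold hangs on 1 unstimulated column with 48.05 CPM of Tnf, since the next highest held 1.14.

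Other lists moved less under TNF. Cell cycle genes lay lower as a set (median −0.40, adjusted p = 0.00233) with 0 of 30 called and 0 over the list alone, and this was lost at adjusted p = 0.19 with an estimated correlation. Glycolysis and hypoxia genes lay higher (median 0.38, adjusted p = 0.00505; adjusted p = 0.131 with an estimated correlation), with 1 of 21 called, also over the list alone, the lactate exporter gene Slc16a3 at 4.26-fold. Sets of NRF2 and oxidative stress genes (adjusted p = 0.0877), actin and adhesion genes (0.099), ribosomal protein genes (0.383), macrophage identity genes (0.71), cholesterol and LXR genes (0.71) and mitochondrially encoded genes (0.797) did not pass. Single members called in them were the autophagy receptor gene Sqstm1 (2.65-fold), the syndecan gene Sdc4 (2.97-fold), the annexin gene Anxa2 (1.89-fold) and Pparg, a regulator of lipid genes, which had 0 counts after TNF and 19.2 ± 46.7 CPM before it (134 in 1 column, at most 12.6 in the others), at least 110-fold lower. Gm14005 fell to 0.0331 and Vps33a to 0.227 of the unstimulated mean. The monocyte antigen gene Ly6c2 was at least 316-fold higher, with 52.8 ± 63.8 CPM. Slc16a3, Ly6c2, Vps33a, Ifit2, Gbp3, Irak2, Pparg and Anxa2 lost their calls with the column number as a block and in limma on mean log2 values, and Saa3, Gbp2, Traf1, Gm14005, Il1b, Cxcl1, Ccl5 and Ifitm3 in limma alone of the settings tried. DESeq2 split its calls 132 higher and 74 lower, and limma 57 and 29, sharing 39 of the 106 edgeR calls.

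**Figure D1:**
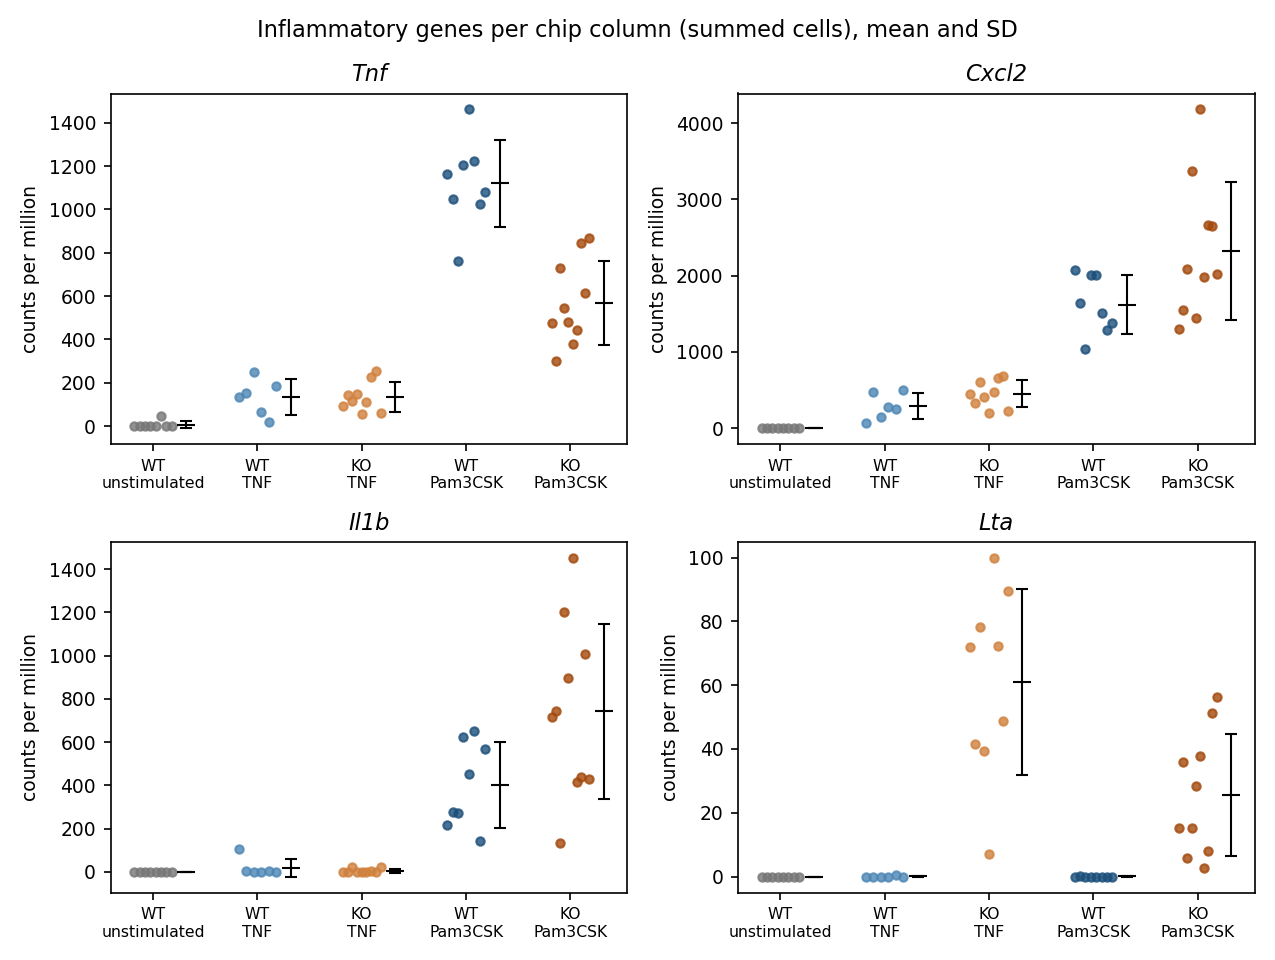
CPM per chip column (points) for Tnf, Cxcl2, Il1b and Lta in the 5 single-cell groups, with the group mean and SD. Cxcl2 and Il1b have 0 counts in the unstimulated columns, and Lta is read in KO columns of both stimuli and at 1 count per group in stimulated WT.

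Pam3CSK raised 237 genes and lowered 37 in WT macrophages relative to unstimulated cells. The largest increases were again in genes nearly silent before. Cxcl2 reached 1621 ± 382 CPM (n = 8), at least 9700-fold above the 0 counts of unstimulated columns (adjusted p = 6.5e-24). Il1b, which encodes the cytokine IL-1 beta, reached 400.4 ± 199 CPM, at least 2400-fold higher, and Saa3 reached 1326 ± 1133 against 0.108 (2 counts). The macrophage chemokine genes Ccl3 and Ccl4 rose 21.6-fold, from 174.6 ± 105 to 3770 ± 537 CPM, and 10-fold, from 428 ± 187 to 4290 ± 992 CPM. Maf, a transcription factor of resident macrophages, fell to 0.252 of its unstimulated 353 ± 122 CPM (adjusted p = 0.000259).

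Cytokines and chemokines had 15 of 21 members higher, 16 over the list alone, with a median log2 fold change of 3.55 (adjusted p = 2.75e-45). Further members were Cxcl1, at least 876-fold higher, Cxcl10, at least 727-fold higher with 121 ± 200.3 CPM (611 in 1 column, at most 103 in the others), Ccl5, 4240-fold higher, and Ccl9, 3.25-fold higher. NF-kB regulators had 23 of 35 higher, 29 over the list alone (median 2.84, adjusted p = 3.06e-76): Clec4e rose 32.1-fold, Nfkbia 25.7-fold, the endocytic gene Ehd1 10.4-fold and Sod2 8.35-fold. Receptor genes had 5 of 22 higher, 5 over the list alone (median 1.05, adjusted p = 3.18e-07), with Tnfrsf1b, TNF receptor 2, up 15.6-fold to 249.5 ± 36.3 CPM, Tlr2 up 12.2-fold, Cd14 up 8.11-fold and Irak2 up 52.7-fold. Interferon-stimulated genes had 4 of 29 higher, 9 over the list alone (median 1.29, adjusted p = 5.07e-09), Ifit2 at least 195-fold. Gbp2 read 105 ± 75.8 CPM against 0.159 (3 counts). Immediate-early genes had 5 of 19 higher, 5 over the list alone (median 0.81, adjusted p = 0.00239), among them Ier3 at 57.3-fold, Junb at 5.58-fold and Atf3 at 5.35-fold. NRF2 and oxidative stress genes had 4 of 20 higher, 5 over the list alone (median 0.58, adjusted p = 1.03e-05): Sqstm1 rose 6.84-fold to 2630 ± 723 CPM, Txnrd1 2.63-fold, Prdx5 2.2-fold and the ferritin gene Fth1 1.59-fold.

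Antigen presentation genes lay higher under Pam3CSK with 3 of 18 called, and 6 higher and 3 lower over the list alone (median 0.89, adjusted p = 0.00912; adjusted p = 0.0939 with an estimated correlation); H2-K1 rose 3.2-fold and the immunoproteasome gene Psmb10 3.61-fold. Cell cycle genes lay lower with 0 of 30 called and 0 over the list alone (median −0.55, adjusted p = 0.00021; adjusted p = 0.0986 with an estimated correlation). The macrophage identity set did not pass (adjusted p = 0.933), while 3 members rose and 1 fell, 4 and 1 over the list alone. Adgre1, which encodes F4/80, rose 3.62-fold, the scavenger receptor gene Marco 118-fold with 500.4 ± 474 CPM, and the transcription factor gene Spi1 2.37-fold, whereas Maf fell. Actin and adhesion (adjusted p = 0.209), mitochondrially encoded (0.22), glycolysis (0.319), ribosomal protein (0.433) and cholesterol genes (0.898) did not pass as sets; Sdc4 rose 3.21-fold and the lipoprotein lipase gene Lpl 2.44-fold. The other large increases, each from 0 counts, were Cdc42ep2 (at least 549-fold), the protease gene Mmp14 (at least 454-fold) and Ccrl2 (at least 392-fold). Dusp6, a phosphatase gene that limits ERK signalling, fell to 0.048 of its mean, Arl4c to 0.0628, Tmem154 to 0.137, Gmnn to 0.208, Trim8 to 0.221 and Mef2c to 0.267. Mef2c lost its call without the cells of lowest total, Mef2c and Trim8 without columns of fewer than 8 cells, and Lpl in limma. Other called list members lost their calls too. With DESeq2 size factors these were Ifitm3, H2-D1 and Anxa2, and without the cells of lowest total Ifitm3 and Anxa2. Without columns of fewer than 8 cells they were Gbp3, Ifitm3 and mt-Co1, and in limma Gbp3, H2-D1, Anxa2 and mt-Co1. The counts split 321 higher and 113 lower in DESeq2 and 375 and 152 in limma.

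Pam3CSK and TNF were then set against each other, in chip columns that shared no number, so chip position goes with the stimulus. In WT, 12 genes were higher with Pam3CSK and 1 lower. Saa3 was 16.1-fold higher (1326 ± 1133 against 82.4 ± 67 CPM), Ccl3 9.49-fold (3770 ± 537 against 397 ± 121, adjusted p = 9.28e-08), Tnf 8.33-fold (adjusted p = 0.0379; 0.0728 in DESeq2), Tnfrsf1b 7.16-fold, Cxcl2 5.6-fold, Ccl4 4.94-fold, Adgre1 3.81-fold and Sqstm1 2.58-fold. Fam20c, a secretory pathway kinase gene, was 3.07-fold and Rassf4 2.34-fold higher, and Il12b, the p40 subunit of IL-12, had 38.5 ± 31.3 CPM against 0 counts, at least 220-fold. The class II gene H2-Aa read 1.11 ± 1.99 CPM with Pam3CSK and 379 ± 607 with TNF, a ratio of 0.00293 (adjusted p = 0.0374), with a very uneven spread over TNF columns. Fam20c lost its call without the cells of lowest total and H2-Aa in limma.

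As sets, cytokines and chemokines lay higher with Pam3CSK (4 of 21 called, 14 over the list alone, median 2.30, adjusted p = 2.85e-29), as did NF-kB regulators (0 of 35 called, 6 over the list alone, median 1.12, adjusted p = 3.13e-15), receptors (1 called, also over the list alone, median 0.32, adjusted p = 0.00479) and NRF2 genes (1 called, 2 over the list alone, median 0.22, adjusted p = 0.000902). Antigen presentation genes lay lower (1 called, 4 over the list alone, median −0.15, adjusted p = 0.0391; adjusted p = 0.236 with an estimated correlation). Interferon-stimulated genes did not pass (median 0.09, adjusted p = 0.57).

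In KO, 17 genes were higher with Pam3CSK than with TNF and 3 lower. Il1b was 149-fold higher (743 ± 405 against 4.98 ± 9.53 CPM, adjusted p = 1.97e-05, n = 10 and 9), Cxcl1 41-fold, Ccl3 6.37-fold, Cxcl2 5.16-fold (2324 ± 909 against 450.2 ± 176.5), Saa3 5.15-fold, Ccl4 3.72-fold and the monocyte chemokine gene Ccl7 2.92-fold. Wfdc17 was 2.83-fold, the kinase gene Syk 2.44-fold, Sqstm1 2.28-fold, Adgre1 2.14-fold, Itsn1 3.48-fold and the mitochondrial ribosomal RNA gene mt-Rnr2 1.66-fold higher. The interferon-stimulated genes Ifit1 (0.757 ± 1.51 against 58.4 ± 108 CPM, with 339 in 1 column and at most 74.6 in the others, ratio 0.013) and Gbp3 (0 counts against 10.8 ± 13.9 CPM, at least 93.2-fold lower) were lower with Pam3CSK. Cytokines and chemokines lay higher as a set (7 of 21 called, 10 over the list alone, median 1.20, adjusted p = 1.65e-16), as did NF-kB regulators (0 called, 6 over the list alone, median 0.51, adjusted p = 0.000548).

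Interferon-stimulated genes lay lower with Pam3CSK in KO (2 of 29 called, 2 over the list alone, median −0.76, adjusted p = 0.000548; adjusted p = 0.124 with an estimated correlation). On the score of this list KO Pam3CSK column 14 stood above the rest of its group, at 4.01, the next at 2.91. Ribosomal protein genes lay higher (0 called, 10 over the list alone, median 0.43, adjusted p = 4.72e-08; adjusted p = 0.137 with an estimated correlation), as did mitochondrially encoded genes (1 called, 4 over the list alone, median 0.50, adjusted p = 0.000548; adjusted p = 0.166 with an estimated correlation). Cell cycle genes (0 called, 1 over the list alone, median −0.29, adjusted p = 0.00119; adjusted p = 0.188 with an estimated correlation; KO TNF column 9, of 5 cells, stood apart on the score of this list at 7.23, the next at 5.89) and antigen presentation genes (median −0.27, adjusted p = 0.00594; adjusted p = 0.124 with an estimated correlation) lay lower. With DESeq2 size factors the split was 19 higher and 13 lower, in DESeq2 56 and 27 and in limma 48 and 42. Cxcl1, Saa3, Syk, Itsn1, Ifit1 and mt-Rnr2 lost their calls without columns of fewer than 8 cells, and Sqstm1 and Gbp3 in limma.

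The difference of Pam3CSK against TNF between the genotypes was tested directly. edgeR called 0 genes, with 457 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0546, 6 genes in DESeq2 and 13 in limma. Of the lists, NF-kB regulators (median log2 difference −0.61, adjusted p = 0.000413) and cytokines and chemokines (−0.61, adjusted p = 0.00126) lay lower in KO, each with 0 genes called and 0 over the list alone: Pam3CSK stood less far above TNF in KO than in WT for these sets. Interferon-stimulated genes also lay lower (0 called, 2 over the list alone, median −0.86, adjusted p = 0.0013; adjusted p = 0.168 with an estimated correlation). Glycolysis genes (median 0.29, adjusted p = 0.0326; adjusted p = 0.266 with an estimated correlation) and ribosomal protein genes (median 0.43, adjusted p = 0.000167; adjusted p = 0.266 with an estimated correlation) lay higher. Over the 7 comparisons, 43 of 98 list tests passed at the preset correlation and 24 with an estimated one.

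Under TNF, KO macrophages differed from WT in 11 genes, 4 higher and 7 lower. Lta, the gene next to Tnf that encodes lymphotoxin alpha, read 61 ± 29.1 CPM in KO (n = 9) against 0.0597 ± 0.146 in WT (n = 6; 1 count; adjusted p = 5.2e-05). Rps2, a ribosomal protein gene, read 897 ± 173 CPM in KO against 2032 ± 276 in WT, a ratio of 0.441, while its processed copies read higher: Rps2-ps6 54.6-fold (57 ± 36.2 against 1.04 ± 1.11) and Rps2-ps10 3.64-fold (1097 ± 324 against 301.5 ± 53). These 3 genes share near-identical sequence, so the division of reads among them is uncertain. The dynein light chain gene Dynlt1b was 2.8-fold higher. Lower in KO were Gm8430 (ratio 0.0467), Gm12918 (0.0594), the mannosidase gene Man1c1 (0.108), the retinaldehyde reductase gene Dhrs3 (0.386; 211 ± 95.5 against 548 ± 170 CPM) and Gm29216 (0.57). Ccl7 (ratio 0.417, adjusted p = 0.0519), Ccl12 (0.283, 0.0764) and Maf (0.336, 0.0563) did not pass.

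NF-kB regulators lay higher in KO than WT under TNF (0 of 35 called, 0 over the list alone, median 0.30, adjusted p = 0.033), a call that fry did not make (adjusted p = 0.0533), and NRF2 genes lay higher (0 of 20 called, 3 over the list alone, median 0.35, adjusted p = 0.000518). Cholesterol and LXR genes lay lower (0 of 27 called, 3 over the list alone, median −0.37, adjusted p = 0.0224; adjusted p = 0.147 with an estimated correlation). Cytokines and chemokines did not pass (median 0.64, adjusted p = 0.118). Man1c1, Rps2-ps6 and Dynlt1b lost their calls with the column block, Dhrs3 and Dynlt1b without the cells of lowest total, and Gm12918 and Man1c1 without columns of fewer than 8 cells. Man1c1 lost its call in limma as well. DESeq2 split its calls 41 higher and 27 lower and limma 207 and 22, the latter with a median log2 shift of 0.24 over all genes.

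Under Pam3CSK, 15 genes were higher and 11 lower in KO than in WT. The Rps2 family moved as under TNF: Rps2 had a ratio of 0.432 (872 ± 148 against 2020 ± 363 CPM, n = 10 and 8), Rps2-ps6 was 105-fold and Rps2-ps10 5.75-fold higher. Lta, named after its values were seen, read 25.7 ± 19.1 CPM in KO against 0.033 (1 count) in WT. H2-Aa read 197 ± 254 CPM against 1.11 ± 1.99, 177-fold higher (adjusted p = 0.0423), a ratio to 27 counts in WT of which 1 column held 20. Tyrobp, an adaptor of myeloid receptors, was 2.19-fold, the cathepsin gene Ctss 1.7-fold, Fxyd5 1.95-fold, Dynlt1b 2.34-fold, Tmem242 4.36-fold, Gm4604 2.82-fold, Rps27rt 3.08-fold and the ribosomal protein gene Rpl13 1.62-fold higher.

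Genes lower in KO under Pam3CSK were Gm8430 (ratio 0.0213), the serine synthesis gene Phgdh (0.0833), Rps12l1 (0.133), Rps16-ps2 (0.241), Parp14 (0.245; 53.6 ± 27 against 219 ± 88.1 CPM), Gm29216 (0.614) and Gbp3, with 0 counts against 15.4 ± 21 CPM, at least 133-fold lower. Interferon-stimulated genes lay lower in KO as a set (1 of 29 called, 8 over the list alone, median −1.18, adjusted p = 3.53e-12), with Ifit1 at a ratio of 0.022 (adjusted p = 0.0661) and Rsad2 at 0.0452 (0.181) short of a call. KO Pam3CSK column 14 stood above the rest of its group on the score of this list, at 4.01, the next at 2.91. NF-kB regulators lay slightly lower (0 called, 0 over the list alone, median −0.20, adjusted p = 0.016). Sets that passed at the preset correlation but not with an estimated one were cytokines and chemokines (median −0.10, adjusted p = 0.0167; adjusted p = 0.0948 with an estimated correlation), macrophage identity (2 called, 3 higher and 1 lower over the list alone, median 0.23, adjusted p = 0.00993; adjusted p = 0.0948 with an estimated correlation) and cholesterol genes (median −0.16, adjusted p = 0.00825; adjusted p = 0.0948 with an estimated correlation). So were actin and adhesion genes (median 0.20, adjusted p = 0.00993; adjusted p = 0.0948 with an estimated correlation) and ribosomal protein genes (2 higher and 1 lower, 3 and 1 over the list alone, median 0.31, adjusted p = 0.00153; adjusted p = 0.314 with an estimated correlation). Of these 5 sets, fry also passed macrophage identity (adjusted p = 0.0282), cholesterol (0.0389) and actin and adhesion genes (0.0282), and not cytokines and chemokines (0.0617) or ribosomal protein genes (0.181). H2-Aa, Ctss, Fxyd5, Tmem242, Rpl13 and Gbp3 lost their calls with the column block, and Dynlt1b, Phgdh and Rps27rt without the cells of lowest total. H2-Aa, Ctss and Tmem242 lost theirs without those cells too. In limma the calls of H2-Aa, Ctss, Fxyd5, Rpl13, Gbp3 and Rps27rt were lost, and with DESeq2 size factors those of Tmem242, Dynlt1b and Rpl13. Without the columns of fewer than 8 cells, which all belong to KO TNF and WT unstimulated and act here only through the shared fit, 41 genes were called, 23 higher and 18 lower.

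The weight of single columns was looked at after the values were seen, over the called genes that the naming rule takes. In 23 of 222 group means of at least 1 CPM, a single column held over 50% of the summed CPM, so folds on these means depend on it. In WT unstimulated these included Traf1 (100%), Tnf (94.5%), Marco (88.8%), Pparg (87.3%), Ier3 (71.5%), Icam1 (69%) and Gm14005 (66.3%). In WT TNF they included Il1b (94.8%), Gbp3 (91.6%), Ifit2 (76.9%), H2-Aa (67.5%), Ccl5 (67%) and Cxcl1 (62.3%), and in WT Pam3CSK H2-Aa (66%), Cxcl10 (62.9%), Dusp6 (54%) and Gbp3 (51.7%). In KO they were Ifit1 (64.4%), Gm12918 (62.6%) and Il1b (51.4%) under TNF and Phgdh (54.3%) under Pam3CSK.

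Of the 30 genes called between KO and WT under either stimulus, 27 had a position and 5 lay on chromosome 17, where 426 of 8378 measured genes lie (5.08%; Fisher's exact p = 0.0106). They were Tmem242 (5410864 to 5440260), Dynlt1b (6429530 to 6440500), Rps2 (24718121 to 24721927), H2-Aa (34282744 to 34287823) and Lta (35203165 to 35205578). The calls of Tmem242, Dynlt1b and H2-Aa were lost in some of the other settings given above, and Fisher's test was not repeated with those settings. That test also treats each gene as independent of its neighbours.

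Single cells were assigned to TNF or Pam3CSK from the expression of 104 list genes. Chip position differed between these stimuli too, and its part in the separation was not tested. In WT, 98.1 ± 2.87% of TNF cells (SD over 6 columns) and 92.6 ± 6.79% of Pam3CSK cells (8 columns) were assigned rightly, 95.4% on average. In KO the shares were 89.3 ± 7.67% (9 columns) and 84.8 ± 10.7% (10 columns), 87% on average. KO minus WT was −8.35 percentage points (permutation p = 0.00408). Without thinning of the cells the difference was −5.12 and did not pass (permutation p = 0.0817). The permutation moved finished column scores between genotypes without training anew. Columns of a genotype were scored by rules trained on mostly the same columns, so their scores are not independent. Random lists gave a median of 64.8% in WT (48.7% to 81%) and 67.8% in KO (53.3% to 74.8%), and 0 of 100 reached the observed share in either genotype.

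**Figure D2:**
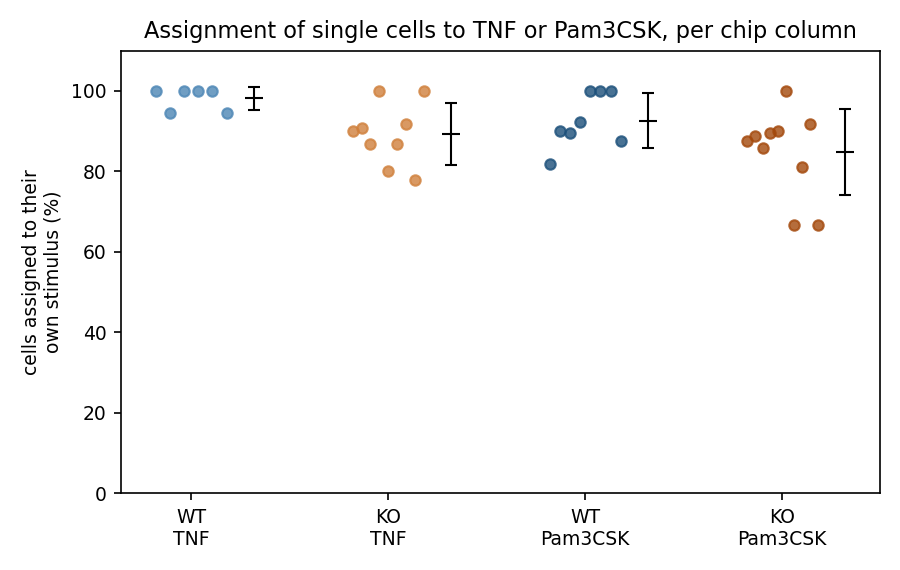
Percent of cells assigned to the right stimulus in each chip column (points), by genotype and stimulus, with the mean and SD over columns. The KO columns average 89.3% under TNF and 84.8% under Pam3CSK, the WT columns 98.1% and 92.6%.

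Cell-to-cell variation was compared for 10 inflammatory genes. In all, 42 of 107 exact permutation tests passed after adjustment, 6 of them between KO and WT. Under TNF a count of Ccl5 was seen in 65.1 ± 26.8% of KO cells and 22.4 ± 23.3% of WT cells (exact permutation, adjusted p = 0.0309). The NF-kB feedback gene Tnfaip3 was seen in 36.8 ± 14.2% and 17.3 ± 8.26% (exact permutation, adjusted p = 0.0259), and Sod2 in 100 ± 0% and 87.7 ± 10.2% (exact permutation, adjusted p = 0.0093). Mean counts per thinned cell were higher in KO as well, at 43.9 against 3.79 for Ccl5, 4.71 against 1.45 for Tnfaip3 and 70.2 against 39.9 for Sod2. Thinned KO TNF cells also held more detected genes in general (median 2895 against 2474), so these shares do not set variation apart from level. The Fano factor was lower in KO than WT under TNF for Cxcl2 (56.4 ± 22.6 against 89 ± 22.8; exact permutation, adjusted p = 0.0443) and Sod2 (22.4 ± 8.58 against 44 ± 20.1; exact permutation, adjusted p = 0.0167). Under Pam3CSK it was higher for Cxcl2 (366 ± 240 against 143 ± 55.6; exact permutation, adjusted p = 0.0428). Il1b was seen in 69.1 ± 16.9% of WT and 72.2 ± 15.9% of KO cells under Pam3CSK, and in 5.38 ± 7.09% and 3.89 ± 6.87% under TNF.

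H3K4me1 rose at 19 regions and fell at none after TNF in WT macrophages, and with the title number as a block 1812 rose and 60 fell. With the replicate characteristic of the labels as the block, which contradicts the title number for some libraries, 0 regions were called. A region inside Il20rb on chromosome 9 (100472848 to 100475319) rose from 0.698 ± 0.183 to 7.36 ± 0.45 CPM (n = 2 each), a log2 fold change of 3.34 ± 0.32 (SE; adjusted p = 0.0239). Regions inside Spint2 on chromosome 7 (29274890 to 29278503; 3.02) and Tbc1d22a on chromosome 15 (86374936 to 86376845; 2.58) rose as well. Regions by NF-kB genes passed only with the block: 1 inside Ripk2 on chromosome 4 (16136659 to 16137985; log2 fold change 2.71, adjusted p = 0.054, blocked 3.5e-06), 1 at 4.32 kb from Birc3 on chromosome 9 (7877526 to 7883081; 1.85, 0.151, blocked 1.78e-05) and 1 inside Nfkb1 on chromosome 3 (135634584 to 135642258; 1.44, 0.181, blocked 8.19e-06). With the block, a region inside Actb on chromosome 5 (142901185 to 142904835) fell by 0.75 on the log2 scale (blocked adjusted p = 0.0277). The 19 calls fell to 0 without WT unstimulated 1, WT unstimulated 2, WT TNF 1, WT Pam3CSK 1, WT Pam3CSK 2 or KO TNF 1, to 2 without KO TNF 2, KO Pam3CSK 1 or KO Pam3CSK 2, and to 10 without WT TNF 2. The blocked 1872 became 747 without WT unstimulated 1 and 801 without WT TNF 1.

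After Pam3CSK in WT, 454 regions rose and none fell; with the block 4791 rose and 1001 fell. The Il20rb region rose by 3.72 ± 0.32 on the log2 scale (adjusted p = 0.00502), and so did regions inside Gm28710 on chromosome 5 (16830759 to 16833575; 3.73), 6.65 kb from Dennd6a on chromosome 14 (26563713 to 26567205; 3.68), 42.1 kb from Arntl on chromosome 7 (113131914 to 113136375; 3.50) and 8.47 kb from Spocd1 on chromosome 4 (129965587 to 129969097; 3.41). Regions by inflammatory genes rose too: 35.5 kb from Il1b on chromosome 2 (129406673 to 129414894; 1.12), 36.8 kb from Il6 on chromosome 5 (29968031 to 29976328; 1.51) and 40.3 kb from Csf2 on chromosome 11 (54200437 to 54207003; 1.06). The Nfkb1 region rose by 2.23 (adjusted p = 0.00759) and the Birc3 region by 2.44 (0.0115). With the block, a region inside the mannose receptor gene Mrc1 on chromosome 2 (14311136 to 14314835) fell by 0.78 (blocked adjusted p = 0.0266). The 454 became 0 without WT unstimulated 1 or WT Pam3CSK 1, 4 without WT unstimulated 2 and 179 without WT Pam3CSK 2. The blocked 5792 became 3200 without WT unstimulated 1, 3533 without WT unstimulated 2 and 2867 without WT Pam3CSK 1.

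In KO macrophages TNF raised 416 regions and lowered none, and with the block 4567 rose and 726 fell. Inside Clptm1 on chromosome 7 (19634499 to 19637659) a region rose from 0.432 ± 0.162 to 14.6 ± 6.2 CPM, a log2 fold change of 4.93 ± 0.56 (adjusted p = 0.00535). The Il20rb region rose by 3.91, a region inside Htr1f on chromosome 16 (64972809 to 64974782) by 3.73, the Dennd6a region by 3.47 and the Gm28710 region by 3.40 (also called at adjusted p = 0.0259). Ripk2 (2.99, adjusted p = 0.00654), Birc3 (2.46, 0.0136), Nfkb1 (2.08, 0.0117) and a region 10.2 kb from Tnfaip2 on chromosome 12 (111465241 to 111473076; 1.43, 0.0298) rose among NF-kB genes, and a region 8.03 kb from the class II transactivator gene Ciita on chromosome 16 (10464416 to 10471980) rose by 1.31 (0.0185). The 416 became 15 without KO unstimulated 1, 80 without KO unstimulated 2, 90 without KO TNF 1, 163 without KO TNF 2, 244 without WT Pam3CSK 1, 248 without WT Pam3CSK 2, 271 without KO Pam3CSK 1 and 276 without KO Pam3CSK 2. The blocked 5293 became 2779 without KO unstimulated 1, 2971 without KO TNF 1 and 3348 without KO TNF 2.

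Pam3CSK in KO raised 278 regions and lowered none, and with the block 3841 rose and 656 fell. Gm28710 (3.71), Dennd6a (3.59), Il20rb (3.29) and a region inside Ift88 on chromosome 14 (57482385 to 57486764; 3.16) led. Nfkb1 rose by 2.23 (adjusted p = 0.0114), Birc3 by 2.41 (0.0177) and the region by Il1b by 0.88 (0.0455), while the region by Il6 passed only with the block (0.99, adjusted p = 0.108, blocked 2.62e-05). The 278 became 0 without KO unstimulated 1 or KO Pam3CSK 2, 7 without KO unstimulated 2, 54 without KO Pam3CSK 1, 151 without WT Pam3CSK 1 and 163 without WT Pam3CSK 2. The blocked 4497 became 2505 without KO unstimulated 1, 2737 without KO unstimulated 2 and 1179 without KO Pam3CSK 2.

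Both LPS libraries, 1 per genotype, had title number 1, while the unstimulated libraries had both numbers, so the fit without the block mixes the stimulus with the title number. With 1 library each, the spread came from the other groups. LPS raised 1061 regions and lowered 3 in WT (blocked 6948 and 1676) and raised 890 and lowered none in KO (blocked 7197 and 2434). A region 13.4 kb from Il10 on chromosome 1 (130996956 to 131006405) rose by 2.85 in WT (adjusted p = 0.00681) and 2.37 in KO (0.0152). The Il6 region rose by 1.90 and 1.51, Nfkb1 by 2.76 and 2.46, Birc3 by 3.01 and 2.66, and a region 3.34 kb from Cd40 on chromosome 2 (165040709 to 165052269) by 1.70 and 1.57. Near the interferon-induced RNA sensor gene Ifih1 on chromosome 2 (62586655 to 62590929, 4.69 kb away) H3K4me1 rose by 1.87 in WT (adjusted p = 0.02) and 1.98 in KO (0.0175), and 6.44 kb from Usp18 on chromosome 6 (121236332 to 121239465) by 2.81 and 2.83. Gm28710 had the largest gain of both genotypes by the naming rule, 4.21 and 4.09. Inside Podxl2 on chromosome 6 (88847514 to 88850998) it fell by 1.55 in WT (0.0177). With the block the log2 fold changes in WT and KO were 3.15 and 2.69 by Il10, 1.845 and 1.495 by Il6, 2.76 and 2.36 at Nfkb1, 2.80 and 2.43 by Birc3 and 1.59 and 1.47 by Cd40. They were 1.97 and 2.08 by Ifih1, 2.53 and 2.56 by Usp18, 3.94 and 3.73 at Gm28710 and, in WT, −1.56 at Podxl2 (all at a blocked adjusted p of 0.00046 or less). The 1064 calls in WT became 0 without WT unstimulated 1 and 235 without WT unstimulated 2, and the blocked 8624 became 4990 without WT unstimulated 1. In KO the 890 became 0 without KO unstimulated 1, 113 without KO unstimulated 2, 552 without WT Pam3CSK 1, 577 without WT Pam3CSK 2, 546 without KO Pam3CSK 1 and 593 without KO Pam3CSK 2, and the blocked 9631 became 5270 without KO unstimulated 1.

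Pam3CSK against TNF gave 0 changed regions in edgeR in WT (1600 at an unadjusted p under 0.05; 33 in DESeq2) and 0 in KO (1294; 4 in DESeq2). With the block, 810 regions were higher and 23 lower with Pam3CSK in WT, and 212 and 138 in KO. The Spocd1 region was higher by 2.82 in WT (blocked adjusted p = 1.95e-06) and 2.61 in KO (4.73e-05), a region inside Clec16a on chromosome 16 (10582776 to 10587110) by 2.31 and 1.78, and the region by Csf2 by 1.14 (1.37e-06) and 0.82 (0.000331). The region by Il1b was higher by 0.70 in WT (0.000399). At Clptm1 Pam3CSK stood below TNF by −1.12 in WT (blocked adjusted p = 0.00164) and −1.96 in KO (1.16e-06), and in KO a region 33.2 kb from Gda on chromosome 19 (21505880 to 21509993) by −1.46. In WT the 0 became 1 without KO unstimulated 1 or KO unstimulated 2, and the blocked 833 became 212 without WT TNF 2 and 245 without WT Pam3CSK 1. In KO the blocked 350 became 111 without KO TNF 1, 152 without KO Pam3CSK 1 and 48 without KO Pam3CSK 2. The difference between genotypes in the TNF response gave 0 regions in edgeR (349 at an unadjusted p under 0.05; with the block 0 and 2621; DESeq2 0), and that in the Pam3CSK response 0 (197; with the block 0 and 1866; DESeq2 0).

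Regions by list genes were tested as sets, and 34 tests passed at the preset correlation while none passed with an estimated one. NF-kB regions lay higher as a set for TNF and Pam3CSK against unstimulated, with adjusted p = 1.89e-12 for WT TNF (adjusted p = 0.417 with an estimated correlation), 3.16e-21 for WT Pam3CSK (adjusted p = 0.126 with an estimated correlation), 1.24e-14 for KO TNF (adjusted p = 0.354 with an estimated correlation) and 8.92e-19 for KO Pam3CSK (adjusted p = 0.235 with an estimated correlation). Of these 148 regions 0 were called in WT TNF (6 adjusted over the list alone), 7 in WT Pam3CSK (28), 5 in KO TNF (19) and 5 in KO Pam3CSK (24); with the block 29, 58, 46 and 49 were higher and 0, 2, 2 and 2 lower. Cytokine and chemokine regions lay higher as a set with adjusted p = 5.37e-07, 1.36e-14, 2.13e-06 and 9.64e-10 in the same order (adjusted p = 0.417, 0.126, 0.354 and 0.235 with an estimated correlation), with 0, 4, 1 and 1 of 116 called and 14, 37, 21 and 28 higher with the block. Interferon-stimulated regions lay higher as a set for WT TNF (adjusted p = 2.93e-07; adjusted p = 0.699 with an estimated correlation), WT Pam3CSK (0.031; 0.946) and KO TNF (9.98e-07; 0.631), with 0 of 104 called in each (with the block 9, 11 and 15 higher, and 1 lower in WT Pam3CSK), and did not pass for KO Pam3CSK (0.193), where the block called 5 higher. They lay lower with Pam3CSK than with TNF in WT (0.0173; 0.734) and KO (1.26e-06; 0.776). For LPS they gave adjusted p = 1.41e-16 in WT (adjusted p = 0.34 with an estimated correlation) with 2 called (blocked 40) and 2.6e-19 in KO (adjusted p = 0.196 with an estimated correlation) with 4 called (blocked 42, and 1 lower). With the block, 3 sets passed for the differences between genotypes that had not passed without it: NF-kB regions (blocked adjusted p = 0.0312) and antigen presentation regions (0.0479) for TNF, and cytokine regions, lower in KO, for Pam3CSK (0.0152). Also with the block alone, cholesterol regions lay lower for LPS in WT (0.0115) and KO (0.00439), macrophage identity regions lower for LPS in KO (0.0397), and ribosomal protein regions lower for LPS (0.0216) and Pam3CSK (0.0383) in KO. For Pam3CSK against TNF in WT, the block added receptor regions, higher (0.0307), and antigen presentation (0.03) and ribosomal protein regions (0.0293), lower, and ended the call of macrophage identity regions (adjusted p = 0.0363, blocked 0.111). None of these passed with an estimated correlation. No list passed for KO against WT.

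KO and WT differed in H3K4me1 mainly on chromosome 17. Averaged over unstimulated, TNF and Pam3CSK libraries, 21 regions were higher and 22 lower in KO, and 43 of the 43 lay on chromosome 17, which holds 4.24% of regions. With the block 152 were higher and 222 lower, 263 of 374 (70.3%) on chromosome 17. In unstimulated cells alone 0 were higher and 2 lower (blocked 39 and 36, of which 66 lay on chromosome 17). The 6 libraries of a genotype are these conditions under title numbers 1 and 2, which paired the libraries. They are therefore not 6 independent samples of the genotype, although the fit treats them so. A region 1.89 kb from Gm6034 (36060539 to 36065730) read 17.1 ± 1.17 CPM in KO against 2.78 ± 0.95 in WT (n = 6 each), a log2 difference of 2.56 ± 0.19 (adjusted p = 0.000521). Around Sik1, a salt-inducible kinase gene, a region at 31869632 to 31876067 was higher by 1.20 and one inside the gene (31826652 to 31845325) read 24.8 ± 5.39 against 73 ± 9.97 CPM, −1.56 on the log2 scale (0.00146). Regions inside Tmprss3 (31178581 to 31183563; 1.49), the cholesterol exporter gene Abcg1 (31107674 to 31111011; 1.37) and Fam234a (26219875 to 26222645; 1.23) were higher, and regions inside Capn15 (25969709 to 25974619; −1.46), Nudt3 (27581329 to 27594592; −1.35) and H2-Q6 (35423408 to 35425925; −1.04) were lower. A region of lower depth by Gm8909 (36166902 to 36168671), named after its values were seen, read 0.0462 CPM in KO against 4.91 in WT. The 2 regions called in unstimulated cells were this one (−7.26) and a region by Sik1 (31800466 to 31802959; −4.50), also named after the values were seen.

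The region that spans Tnf and Lta (35182907 to 35237356) read 269 ± 34.7 CPM in KO and 262 ± 40.1 in WT, a difference of 0.04 ± 0.14 (adjusted p = 1). It also spans Atp6v1g2, Lst1, Ltb and Nfkbil1 and is far wider than the median region of 2035 bp. A local change at Tnf or Lta could be diluted in it, so this value does not exclude one. Of the blocked calls on chromosome 17, 261 of 1737 tested regions below 40 Mb were called (15%) and 2 of 2049 above it. The WT libraries of title number 1 differed from the other 10 on the sex chromosomes: they held 0 to 0.202 CPM in Y regions against 75.1 to 95.7, and 19.9 to 21.4 CPM at the region near Xist, the gene of the X-inactivating RNA, against 0.509 to 1.67. With the block 9 regions on X were called between genotypes, and within title number 1 the genotypes also differed in these sex-linked values. Scaling by total counts in regions gave 12 higher and 19 lower. The 43 calls became 26 without WT unstimulated 2, 27 without WT TNF 2, 25 without WT Pam3CSK 1, 23 without WT Pam3CSK 2, 25 without KO Pam3CSK 1 and 27 without KO Pam3CSK 2. The 2 calls in unstimulated cells became 0 without KO unstimulated 2 and 1 without any 1 of WT unstimulated 1, WT unstimulated 2, WT TNF 1, WT TNF 2, WT Pam3CSK 1, WT Pam3CSK 2, WT LPS 1, KO unstimulated 1, KO Pam3CSK 1 and KO Pam3CSK 2; the blocked 75 became 35 without WT unstimulated 1 and 39 without KO unstimulated 1. Title number 1 alone called 2405 regions, 391 of them on chromosome 17 (16.3%), and title number 2 alone 323, 188 of them there (58.2%). Within a title number the libraries of a genotype are its different stimuli, so these counts have no labelled replicate of genotype.

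**Figure D3:**
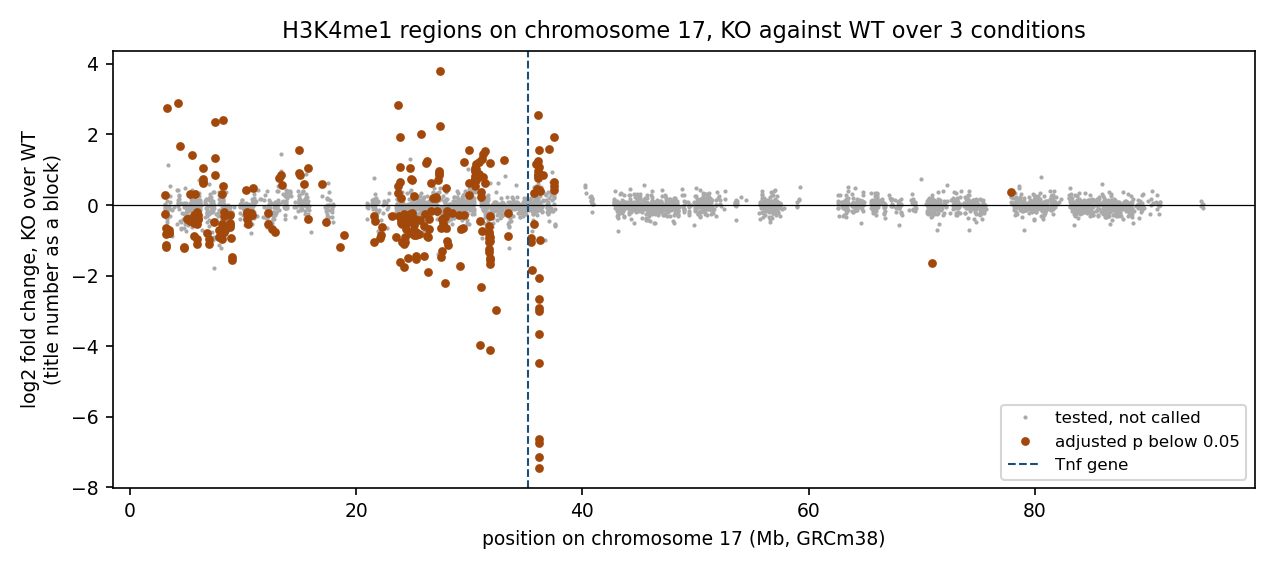
Log2 difference in H3K4me1 between KO and WT along chromosome 17 (position in Mb), averaged over 3 conditions with the title number as a block; called regions are orange and the dashed line marks Tnf. Called regions lie from 3089516 to 37508500 bp, except 2 above 40 Mb.

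**Figure D4:**
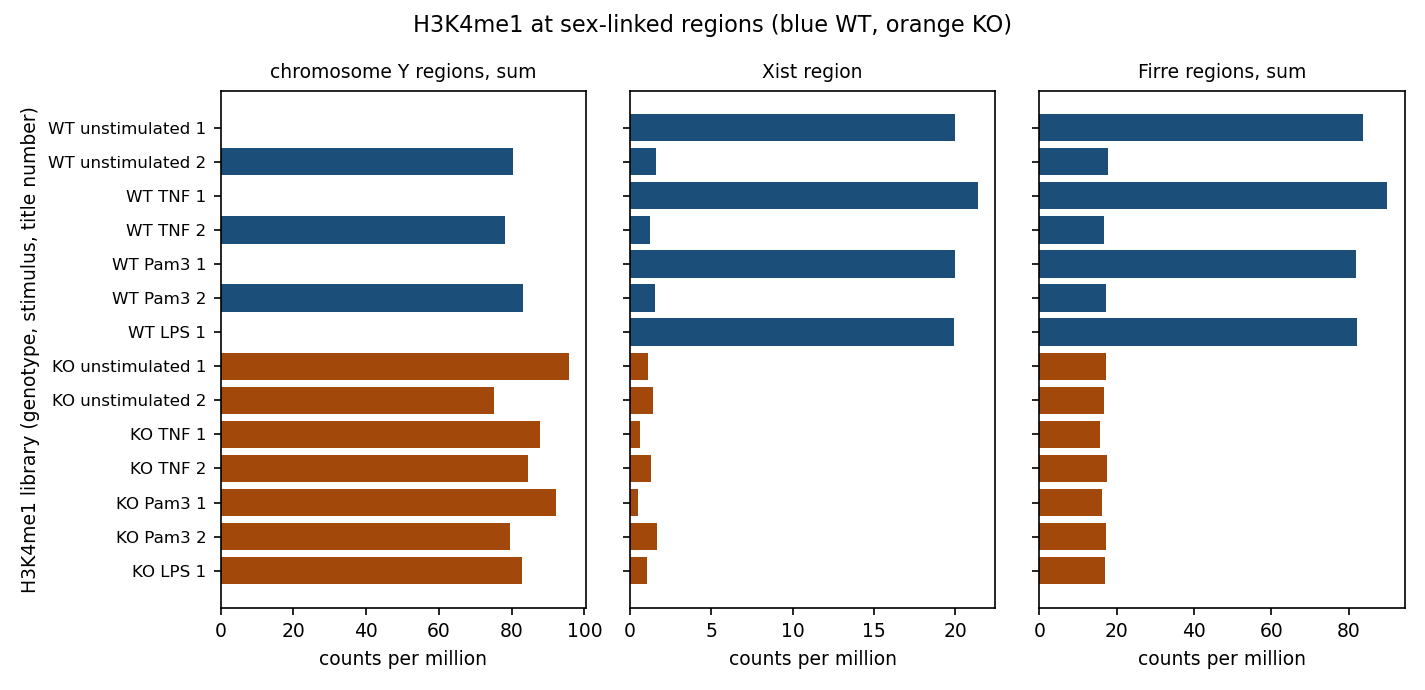
CPM in regions on Y, near Xist and at Firre for each of the 14 H3K4me1 libraries (bars; WT blue, KO orange). The WT libraries of title number 1 hold 0 to 0.202 CPM on Y, and the other 10 hold 75.1 to 95.7.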

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

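Of the tests in this part, those of noisier KO cells and of fewer detected genes in KO cells were chosen after the result was seen; the rest were planned.

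Assignment of single cells to their stimulus was less often right in KO than in WT columns, by −8.35 percentage points (permutation p = 0.00408). That p-value covers only the spread of column scores that are not independent within a genotype. Fewer detected genes in KO cells at equal depth is argued against, since thinned KO cells held 218.5 more genes than WT cells at the median in the stimulus with the smaller difference. All cells were thinned to the same count, so this measure does not test depth. Noisier KO cells that separate less well on any genes could not be excluded: the median KO minus WT difference over 100 random lists was 2.79 points, but 8 of the 100 lists reached −8.35 or lower. Columns of the same number in KO and WT came from different chips, and 0 labels name the chip of a column. A difference between chips therefore cannot be told apart from genotype. A biological difference between the genotypes stays open as a hypothesis, with the limit that without thinning the difference was −5.12 points and lost its call (permutation p = 0.0817). It was not tested here; cells of both genotypes on the same chip would test it.

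The difference of Pam3CSK against TNF between KO and WT had a median log2 value of −0.609 over cytokines and chemokines, −0.608 over NF-kB regulators and −0.856 over interferon-stimulated genes, and of 0.287 over glycolysis genes and 0.434 over ribosomal protein genes. With an estimated correlation the first 2 passed, at adjusted p = 0.0286 and 0.00168, and the others did not.

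Single chip columns stood far from the rest of their group in 12 of 95 groups of values tested over 19 measures; chance alone marks about 1 in 20. Column 10 of KO TNF held 6697999 counts, against 2634482 in the next. Column 11 of KO Pam3CSK detected 6941 genes, against 7709. Column 9 of WT unstimulated had 4.47% mitochondrial reads, against 6.47%, a cholesterol gene score of 5.31 against 6.18 (mean log2 CPM, as for the scores that follow) and a ribosomal protein score of 9.25 against 10.1. Column 7 of WT unstimulated held Tnf at 48.05 CPM, against 1.14. Column 5 of WT unstimulated had a cytokine score of 3.96 against 3.16 and an actin and adhesion score of 7.81 against 8.20. In KO Pam3CSK, column 14 had an interferon-stimulated score of 4.01 against 2.91 and column 16 an NRF2 score of 9.2 against 8.63. Column 9 of KO TNF had a cell cycle score of 7.23 against 5.89, and column 10 of WT TNF a ribosomal protein score of 9.69 against 10.4.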

How the results depend on the processing

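The fit without columns of fewer than 8 cells, the fits without X and Y and within each title number, leave-one-out within the blocked fit and the blocked list test at an estimated correlation were chosen after seeing the data; all other settings were planned. No named gene or region that was called turned its direction. The balance of calls turned for KO against WT: under TNF 4 were higher and 7 lower, against 41 and 27 in DESeq2 and 207 and 22 in limma. Under Pam3CSK 15 were higher and 11 lower, against 10 and 12 with the column block and 12 and 13 with DESeq2 size factors. Cholesterol and LXR regions, not called for LPS without the block (median 0.0664 in WT and 0.0796 in KO), were lower with it (−0.138 and −0.12). Over the comparisons of single cells 47 alternatives stayed within the main call or 1.5 times the main count, 16 gave more and 3 less. The setting without a filter, counted among those that stayed, repeats the main fit, since the default filter kept all 8906 genes. For H3K4me1 328 stayed, 23 gave more and 83 less. Of single genes 2728 alternatives kept the call, 120 gained and 99 lost it, and of single regions 13700, 353 and 483. Few simulated 2-fold changes were recovered in the single-cell sums; whether depth or the spread between columns limits them was not tested. The cause of each change below was not tested.

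Single-cell counts, in the order WT TNF and WT Pam3CSK against unstimulated, Pam3CSK against TNF in WT and in KO, KO against WT under TNF and Pam3CSK, and the difference between genotypes, were 106, 274, 13, 20, 11, 26 and 0. DESeq2 gave 206, 434, 93, 83, 68, 53 and 6. In limma on mean log2 values, all but the first moved beyond 1.5 times, to 527, 122, 90, 229, 61 and 13. DESeq2 size factors gave 32 for Pam3CSK against TNF in KO. Without columns of fewer than 8 cells, none of which belong to the groups compared, Pam3CSK against TNF in WT gave 28 and KO against WT under Pam3CSK 41. Column numbers did not pair the samples: deviations correlated at a median r of 0.00565 over 27 pairs of columns with the same number, 1 of them above 0.1, and at 0.000274 over 641 other pairs. With the column number as a replicate block KO against WT under TNF gave 7 genes; 81, 22 and 0 were called for WT TNF, for KO against WT under Pam3CSK and for the difference. No paired analysis was possible in the other 3 comparisons, which shared no column number. Unstimulated and TNF columns were numbered 1 to 10 and Pam3CSK columns 11 to 20, so chip position cannot be told apart from Pam3CSK there. An estimated correlation left 24 of the 43 list calls. The cell assignment gave −5.12 points without thinning and passed under the other settings tried.

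For H3K4me1, the title number as a replicate block gave 75 regions for unstimulated KO against WT, 374 averaged, 1872 for WT TNF, 5792 for WT Pam3CSK, 5293 for KO TNF, 4497 for KO Pam3CSK, 8624 for WT LPS, 9631 for KO LPS, and 833 and 350 for Pam3CSK against TNF in WT and KO. The other 2 comparisons, the differences between genotypes, stayed at 0 with it; list and region calls that it changed stand in the results above. The crossed numbering of the replicate characteristic as a replicate block gave 0, 253, 191, 125, 622 and 197 for WT TNF, WT Pam3CSK, KO TNF, KO Pam3CSK, WT LPS and KO LPS. DESeq2 gave 13 for unstimulated KO against WT, 70 averaged, 178 for WT TNF, 646 for KO TNF, 429 for KO Pam3CSK, and 33 and 4 for Pam3CSK against TNF in WT and KO. Total counts gave 9 for WT TNF and 706 for WT LPS. For Pam3CSK against TNF in WT, DESeq2 size factors and leaving out X and Y each gave 1. Averaged KO against WT gave 2405 within title number 1 and 323 within number 2. With an estimated correlation 0 list calls were left, with or without the block.

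Leaving out 1 ChIP library at a time gave these lowest and highest counts without the block: 0 and 2 for unstimulated KO against WT, 23 and 43 averaged, 0 and 19 for WT TNF, 0 and 474 for WT Pam3CSK, 15 and 423 for KO TNF, 0 and 287 for KO Pam3CSK, 0 and 1257 for WT LPS, 0 and 1219 for KO LPS, 0 and 1 for Pam3CSK against TNF in WT, and 0 in KO and for both differences between genotypes. With the block they were 35 and 85, 258 and 438, 747 and 2042, 2867 and 5952, 2779 and 5588, 1179 and 4635, 4990 and 9124, 5270 and 9928, 212 and 896 in the same order, 48 and 455 for Pam3CSK against TNF in KO, and 0 for both differences.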

Other observations

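Of the tests in this part, those of TNF-responsive regions, of the summed Rps2 family and of the other ribosomal protein genes were chosen after the result was seen. The fit within title number 2, on which the test of a sex difference rests, was also chosen after seeing the data. The test of TNF-responsive regions replaced an earlier one, the share of called chromosome 17 regions also called for TNF (5 of 263, 1.9%, exact 95% interval 0.62% to 4.38%, against 2.1% of all regions), which did not decide.

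Sex-linked regions divided the H3K4me1 libraries in a way that goes against the labels, which describe the mice as matched for sex. The 4 WT libraries of title number 1 held 82 to 90 CPM in the regions at Firre, an X-linked gene, against 15.8 to 17.8 CPM in the other 10, besides the values on Y and near Xist given above. In the single-cell columns the Y genes Ddx3y, Eif2s3y, Kdm5d and Uty were read in every group. A region 30.1 kb from Pim1, a kinase gene of the NF-kB list, on chromosome 17 (29456467 to 29460653) was lower in KO by −0.65 on the log2 scale with the block (blocked adjusted p = 1.96e-05) and not called without it (adjusted p = 1). On the unplaced sequence JH584304, 9 of 9 tested regions were called between KO and WT with the block.

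Differences between KO and WT in H3K4me1 gathered on chromosome 17 below 40 Mb, a stretch that holds the targeted gene. A sex difference between the animals of title number 1 is argued against as the source, since 58.2% of the regions called within title number 2 alone lay on chromosome 17. An action of TNF through TNF-responsive regions was not decided. Of the regions called for TNF in WT with the block, 4.49% (84 of 1872) lay on this chromosome, against 4.24% of all regions. Without the block 0 of 19 lay there. The response to added TNF was thus not gathered on chromosome 17. Such a share could arise whatever gathered the KO differences, so no conclusion on the loss of TNF is drawn from it. A strain variant segment carried along with the Tnf allele may account for the pattern, and 98.5% (259 of 263) of the called chromosome 17 regions had the same sign between the LPS libraries. These stand outside the contrast but share its fit and the title number 1 with part of its libraries, so they are not independent of it. The same held for 94.6% (88 of 93) of calls on other autosomes, so this test is not specific to a segment, and no sequence was examined.

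In KO, Rps2 read lower while Rps2-ps6 and Rps2-ps10 read higher, under both stimuli. Lower expression of ribosomal protein genes in general is argued against, because the other 25 had a median log2 difference of 0.32 under Pam3CSK (−0.13 under TNF), against −1.21 for Rps2. Reads moved from Rps2 to its pseudogenes by a sequence variant in KO DNA may account for it: the summed CPM of the 3 genes had a KO over WT ratio of 0.878 under TNF (exact permutation p = 0.192) and 0.977 under Pam3CSK (exact permutation p = 0.779). Rps2 lies on chromosome 17 at 24718121, inside the stretch of H3K4me1 differences, and variants were not called here.

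Other splits of the same samples into groups of the same sizes were drawn to ask whether chance could give the counts. For WT TNF against unstimulated 1 of 100 splits, the real one with 106 genes, reached that count, and the highest other gave 44. The real split also stood highest for WT Pam3CSK against unstimulated (1 of 100, 274 genes, highest other 47) and WT Pam3CSK against TNF (1 of 100, 13, highest other 2). It did so for KO Pam3CSK against KO TNF (1 of 100, 20, highest other 0), and for KO against WT under TNF (1 of 100, 11, highest other 2) and Pam3CSK (1 of 100, 26, highest other 2). These splits treat columns as separate samples. A difference between chips, cultures or mice would also set the real split apart, so chance at that level was not excluded. For the difference between genotypes all 100 of 100 splits reached the real count of 0, with 2 as the highest other. For H3K4me1 between KO and WT without the block, 10 of 60 splits reached 43 regions and the highest other gave 48585, so chance was not excluded there. The median of the other splits was 0 regions. Whether the splits with many calls follow the title number was not recorded. With the title number as a block, which parts every pair, 1 of 32 splits reached the real count of 374, and the highest other gave 39. Libraries of 1 genotype and title number may share a source, while these splits swap them pair by pair. They therefore do not exclude chance between animals or preparations.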
